A study of Mus musculus with 12 samples.

How the data were processed

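Expression was measured in the colon of healthy male mice, 12 to 16 weeks old, of 4 genotypes: wild type, LAO1 knockout, IL4i1 knockout and the double knockout that lacked both genes. Il4i1 and Lao1 encode secreted L-amino acid oxidases, enzymes that turn amino acids into keto acids with release of ammonia and hydrogen peroxide. Each genotype was represented by 3 Affymetrix arrays, 12 in all, and groups and replicate numbers were taken from the sample labels. Per the labels' protocols, 4 mice were chosen at random for each genotype. Whether each array held the RNA of a single mouse is not given in the sources used here, so p-values measure the spread between these samples, which may be partly technical.

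Per the labels' protocols, total RNA was extracted with ISOGEN II and 6 µg of it was turned into biotin-labelled cRNA for hybridisation. The submitters' processing notes name Transcriptome Analysis Console, without a version. The authors deposited log2 expression values in a table of 22206 probes by 12 arrays, given to 2 decimals and lying between 1.72 and 19.93. The summarisation and normalization method is not given in the sources used here, and neither is the genome build, so no coordinates are printed. The array medians lay between 5.42 and 5.49, and the values were used as deposited, with no further normalization and no filter. For arrays no read depth exists, and the number of arrays limits the precision. A value near the bottom of the range carries no reliable level, and 22 probes reached the highest value of the table on at least 1 array.

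Probe names came from the platform annotation, which can be old. Of the probes, 19572 had 1 gene symbol, 0 had several and 2634 had none given. All 19505 named genes were looked up by Entrez number in a RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols and served otherwise to find neighbouring genes; 55 genes had more than 1 probe, each tested separately. Gene lists used 1 probe per gene, that with the highest mean over all arrays.

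Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) in 1 fit over all 12 arrays with a mean per genotype, which left 8 residual degrees of freedom. The comparisons were the double knockout, the LAO1 knockout and the IL4i1 knockout each against wild type, the double knockout against each single knockout, and the interaction. The interaction was the double knockout less both single knockouts plus wild type, on the log2 scale. Every p-value of a gene is limma's two-sided one, adjusted by the Benjamini-Hochberg method over all 22206 probes of the comparison, with a threshold of 0.05 and no minimum fold. A log2 difference is given with its standard error (SE) from that fit, and a group mean with its SD over 3 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

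The shift of 40 gene lists was tested with camera, the competitive test of limma that compares a list with all other named genes, at its preset correlation between genes of 0.01. The p-values were adjusted over the lists of a comparison. Alternatives were camera with the correlation estimated from the data, and fry. The p of fry asks whether the genes of a list move, on balance, one way and does not compare them with other genes. The lists covered the kynurenine pathway, aryl hydrocarbon receptor targets, phenylalanine and tyrosine catabolism, hydrogen peroxide and superoxide enzymes, amino acid transporters, ATF4 stress response targets, inflammatory cytokines, chemokines and acute phase genes, the interferon response, MHC class II antigen presentation, antimicrobial proteins, goblet cells and mucus, tight and adherens junctions, ion and water transport, absorptive colonocytes, stem cells and proliferation, enteroendocrine cells and serotonin, tuft cells, T and innate lymphoid cells, B cells, plasma cells, macrophages, monocytes and dendritic cells, neutrophils, mast cells and eosinophils, smooth muscle, enteric neurons and glia, fibroblasts and extracellular matrix, endothelial cells, adipocytes, pancreatic acinar cells, small intestine, posterior Hox genes, the circadian clock, immediate early and heat shock genes, glucocorticoid targets, bile acid and xenobiotic metabolism, PPAR targets and fatty acid oxidation, cholesterol synthesis, oxidative phosphorylation, and the genes beside Lao1 and beside Il4i1 on their chromosomes. Some genes stand in more than 1 list, among them Saa1, Lcn2, Zg16 and Mylk.

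The tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named Il4i1 and Lao1 in every comparison, and in each comparison the 10 largest rises and the 10 largest falls among named genes past the threshold. Where no more than 5 probes passed in both directions together, the 5 smallest unadjusted p-values in each direction were added as not past it. From each shifted list it took the 4 members with the smallest p in the direction of the shift, and from the other lists up to 3 members past the threshold. Ido1, Kynu, Kmo, Cyp1a1, Ahrr, Tph1, Slc26a3, Aqp8, Lcn2, Reg3b and Reg3g were named in the double knockout against wild type whatever their p. A gene named outside this rule is said to have been chosen after its values were seen.

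The analysis was tested on simulated data made from the means and spreads of these arrays, with 200 of 22206 probes changed and genes independent of each other. At a log2 change of 2, in the order of the comparisons, 98%, 94%, 96%, 94%, 97% and 71% of changed probes were recovered. At a log2 change of 1 the shares in that order were 30%, 28%, 29%, 18%, 34% and 9%, and false calls numbered 5, 7, 6, 1, 12 and 4. Camera with either correlation and fry called a raised list each time, and preset camera called 0 others. Independent genes cannot show false calls of correlated lists. In 3 arrays against 3 there are 10 splits, and the smallest two-sided exact p is 0.1, so no permutation test of a single gene was used between genotypes.

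The alternatives were an added 2-fold minimum, an adjusted p threshold of 0.1, an unadjusted p of 0.05 with a 2-fold minimum, array weights, leaving out each array in turn, a fit to the arrays of the genotypes compared, a filter that kept probes with a mean above the 40th percentile (4.67), the trend and robust options, a block for the replicate number, median centring and quantile normalization. Refits without the arrays that stood apart, IL4i1 knockout replicate 2 and double knockout replicates 1 and 2, were added after the data had been seen. For the similarity of effects that share arrays, 100 simulations with unchanged groups gave the correlation that sharing alone produces if all genotypes have the same spread.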

Results

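Gene expression in the colon was compared between wild type mice and mice lacking LAO1, IL4i1 or both enzymes, with 3 arrays per genotype. The study asked what the loss of both L-amino acid oxidases does to the colon, with inflammation and the IDO1-kynurenine route of tryptophan use among its subjects. Each of the 12 arrays gave a log2 value for 22206 probes. Pairwise correlations across probes lay between 0.964 and 0.99, and any 2 arrays held equal values at 0.581% to 1.17% of probes, so no array was a copy of another. The first 3 principal components held 20.2%, 16.5% and 13.4% of the variance. IL4i1 knockout replicate 2 stood apart on the first, at 68.94 against -40.03 to 20.75 for the other 11 arrays. Double knockout replicate 1 lay highest on the second (61.67, others -25.68 to 29.93) and replicate 2 on the third (56.85, others -31.72 to 17.65).

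The targeted genes were examined first. No probe bore the name Il4i1, and the gene was not analysed here. The Lao1 probe was dim on every array, with 3.24, 3.12 and 2.64 in wild type, 3.1, 2.68 and 3.24 in the LAO1 knockout, 2.98, 3.33 and 3.16 in the IL4i1 knockout, and 3.23, 3.41 and 3.56 in the double knockout. Its mean was 3 ± 0.32 in wild type and 3.01 ± 0.29 in the LAO1 knockout (SD, n = 3). The difference between these groups was 0.01 (SE 0.22, adjusted p = 1), that of the double knockout from wild type 0.4 (adjusted p = 0.74), and that of the IL4i1 knockout from wild type 0.16 (adjusted p = 0.893). Against the LAO1 and the IL4i1 knockout the double knockout differed by 0.39 and 0.24 (adjusted p = 0.784 for both), and the interaction was 0.24 (adjusted p = 0.935). The place of this probe relative to the deleted part is not given in the sources used here, and at this level it checked nothing, so the genotypes rest on the labels.

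In the double knockout against wild type, Sh3d19, which encodes an adaptor protein with SH3 domains, rose 7.31-fold, from a log2 level of 11.98 to 14.85. The extracellular heparan sulfate sulfatase Sulf2 rose 3.56-fold, from 7.93 ± 0.1 to 9.76 ± 0.46. The stress-induced transcription cofactor Nupr1 fell by 3.61 on the log2 scale, from 13.42 ± 0.69 to 9.82 ± 0.13. Hao2, a peroxisomal 2-hydroxy acid oxidase, fell by 2.39, and the core clock activator Arntl by 2.48. All 3 double knockout arrays lay beyond all 3 wild type arrays for each of the 5 genes (SD, n = 3).

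These 5 were the probes that passed limma's test, 2 higher and 3 lower, while 1653 had an unadjusted p under 0.05. The log2 differences were 2.87 for Sh3d19 (SE 0.19, adjusted p = 2.31e-05), -2.39 for Hao2 (SE 0.28, adjusted p = 0.00974), 1.83 for Sulf2 (SE 0.25), -3.61 for Nupr1 (SE 0.49) and -2.48 for Arntl (SE 0.35), the last 3 at an adjusted p of 0.0352. Next in order of p, and not past the threshold, stood Sult1c2 (-1.91, adjusted p = 0.0582), Fen1 (1.78, 0.0692), Gm4951 (2.53) and Sae1 (1.24; both 0.0716), and Trpm6 (-2.57) and Gbp3 (1.99; both 0.0744). Without wild type replicate 2 only Sh3d19 passed. The count was 38 without double knockout replicate 2. It was 3, 2 and 3 without wild type replicate 1 and double knockout replicates 1 and 3. With only the compared arrays 1 higher and 1 lower passed, so some of the 5 were lost. Of the 5 genes Sh3d19 passed in all traced runs.

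The genes of interferon responses, which guard cells against viruses and intracellular microbes, stood higher as a list in the double knockout than in wild type, with a mean log2 difference of 1.11 over 31 measured members (camera, adjusted p = 5.9e-19). With an estimated correlation the adjusted p was 0.113, and with fry 0.0326. Over all genes 0 members passed limma's test, 19 had an unadjusted p under 0.05, all higher, and 17 passed when adjusted over the list alone. The guanylate-binding proteins Gbp2 (3.06) and Gbp7 (1.72; both adjusted p = 0.229) and the immunity-related GTPase Igtp (3.1, 0.128) were among them. The mean of the list was 8.23 ± 0.34 in the double knockout and 7.12 ± 0.39 in wild type (SD, n = 3), with all 3 arrays of the double knockout above those of wild type. MHC class II genes, which present antigen to helper T cells, had a mean difference of 1.02 over 10 members (adjusted p = 7.55e-07, adjusted p = 0.48 with an estimated correlation), again with 3 of 3 arrays above. None passed over all genes (0, against 6 at an unadjusted p under 0.05), and 6 passed adjusted over the list alone, among them H2-DMb1 (2.03), H2-Aa (1.51), H2-Ab1 (1.35) and H2-Eb1 (1.02). T and innate lymphoid cell markers differed by 0.25 (adjusted p = 0.0301, and 0.48 as the adjusted p with an estimated correlation), and Gzma (1.54) passed adjusted over the list alone.

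**Figure D1:**
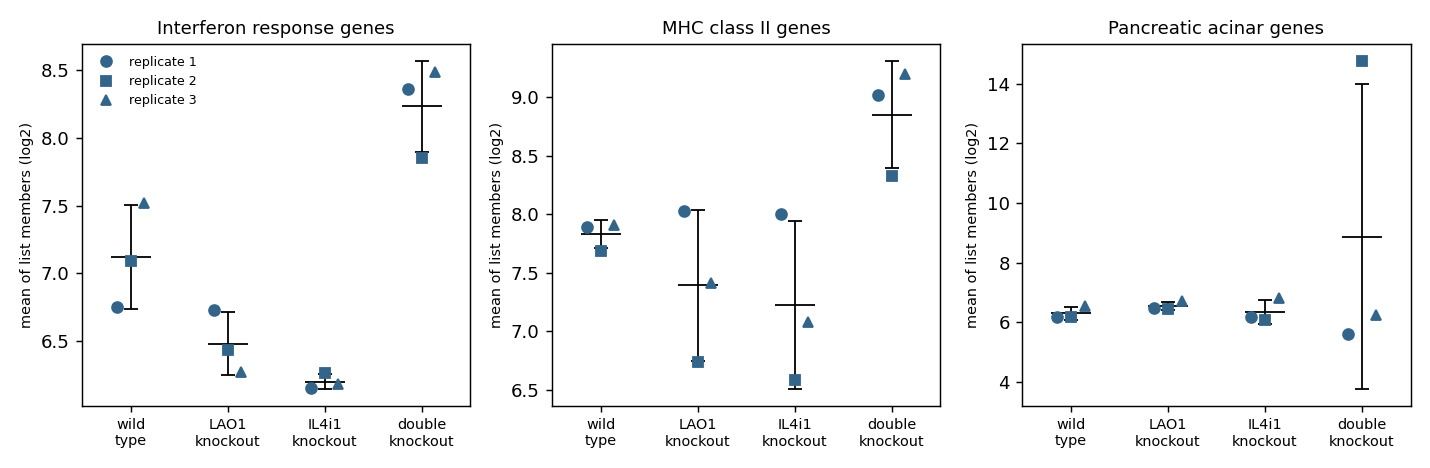
Mean log2 value of the members of the interferon response, MHC class II and pancreatic acinar lists (vertical axis, log2) in the 4 genotypes (horizontal axis), with points for the 12 arrays and bars for the group mean and SD. Interferon means lay at 7.85 to 8.49 in the double knockout and at 6.15 to 7.52 elsewhere, and the acinar mean was 14.77 in double knockout replicate 2 and 5.59 to 6.8 in the other arrays.

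Inflammatory cytokines, chemokines and acute phase genes had a mean difference of 0.68 over 36 members (adjusted p = 1.75e-06, adjusted p = 0.48 with an estimated correlation). Among them 0 passed over all genes or adjusted over the list alone in limma's test, and 10 had an unadjusted p under 0.05, 9 higher and 1 lower. Cxcl9, a chemokine that draws activated T cells, stood 4.01 above wild type (SE 1.17, adjusted p = 0.444), and Cxcl10, Ifng and Il1b by 1.69, 0.91 and 2.36. The list mean was 6.36 in double knockout replicate 1 and 4.64 to 5.15 in the other 11 arrays. The neutrophil and epithelial iron-binding protein Lcn2 reached 9.81 in that array against 3.17 to 3.94 elsewhere, so its difference of 1.95 (SE 1.18, adjusted p = 0.763) turned to -0.16 without it. The antimicrobial lectins Reg3b (4.9, SE 2.87, adjusted p = 0.75) and Reg3g (3.17, SE 2.44, adjusted p = 0.825) were likewise highest there, and without it Reg3g stood at -1.02.

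Ido1, which opens the kynurenine pathway by oxidising tryptophan, was at 14.85, 7.88 and 11.14 in the double knockout arrays and at 3.4, 5.93 and 7.91 in those of wild type. The difference of 5.54 (SE 1.34) did not pass over all genes (adjusted p = 0.345) and did pass adjusted over the list alone, the only 1 of 13 members to do so. Kynu and Kmo, further enzymes of the pathway, differed by 0.0 (adjusted p = 0.997) and 0.3 (0.858). Cyp1a1 and Ahrr, targets of the aryl hydrocarbon receptor, differed by -0.09 (0.964) and 0.13 (0.939). As a list the kynurenine pathway did not pass (mean 0.47, adjusted p = 0.291), and neither did the aryl hydrocarbon receptor targets (0.04, 0.682) or phenylalanine and tyrosine catabolism (0.07, 0.57).

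Absorptive colonocyte markers had a mean difference of -0.69 from wild type over 18 members (adjusted p = 0.0151, adjusted p = 0.48 with an estimated correlation), with 0 past over all genes, 3 at an unadjusted p under 0.05 and 2 adjusted over the list alone, Mep1a (-2.29) and Ceacam20 (-1.91). Ion and water transport genes followed at -0.25 over 30 members (adjusted p = 0.0141, adjusted p = 0.208 with an estimated correlation), where 0 members passed over all genes, 7 had an unadjusted p under 0.05 and Slc26a2 (-1.05) and Aqp7 (-0.96) passed adjusted over the list alone. The chloride-bicarbonate exchanger Slc26a3 (-0.67, adjusted p = 0.818) and the water channel Aqp8 (-1.7, 0.691) did not pass. Goblet cell genes stood at -0.35 (adjusted p = 0.0116; Spdef -1.11) and enteroendocrine genes at -0.29 (0.0117; Chgb -1.3), with an adjusted p of 0.513 and 0.208 with an estimated correlation. Tph1, the enzyme of serotonin synthesis in these cells, stood at -0.33 (adjusted p = 0.911). In each of these last 2 lists 0 members passed over all genes or adjusted over the list alone, with 1 and 3 at an unadjusted p under 0.05.

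Stem cell and proliferation genes stood higher in the double knockout, by 0.51 over 23 members (adjusted p = 9.18e-06, adjusted p = 0.48 with an estimated correlation). Adjusted over the list alone 5 passed, the replication genes Mcm3 (1.4), Mcm4 (1.26), Mcm6 (1.74), Pcna (1.05) and Rrm2 (1.09), against 0 over all genes and 8 at an unadjusted p under 0.05. Targets of the amino acid stress factor ATF4 stood 0.25 higher (adjusted p = 0.0203, adjusted p = 0.493 with an estimated correlation). The serine synthesis enzyme Phgdh stood at 1.09 and Shmt2 at 1.18, while Nupr1, also in this list, was the 1 member of 19 that fell. Immediate early and heat shock genes stood at -0.67 (adjusted p = 0.00683, adjusted p = 0.493 with an estimated correlation), led by the heat shock proteins Hspa1b (-3.41) and Hspa1a (-2.67), which alone passed adjusted over the list alone (2, against 0 over all genes and 6 at an unadjusted p under 0.05). Wild type replicate 2 held the highest Hspa1b value, 12.79, against 6.42 to 9.38 in the other arrays.

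Pancreatic acinar genes had a mean difference of 2.57 (adjusted p = 0.00347, adjusted p = 0.523 with an estimated correlation) that came from double knockout replicate 2. The carboxypeptidase gene Cpa1 was at 18.12 in that array and at 4.21 to 5.48 in the others. Without that array the list stood at -0.38 (adjusted p = 0.179). It had 0 members past over all genes, over the list alone or at an unadjusted p under 0.05. Smooth muscle stood at -0.46 (adjusted p = 0.00205; Mylk -1.11), adipocytes at -0.65 (0.00702; Adipoq -1.63), PPAR targets and fatty acid oxidation at -0.31 (0.0203; Cd36 -1.6) and endothelial cells at -0.35 (0.0204; Lyve1 -1.05). With an estimated correlation the adjusted p was 0.522, 0.48, 0.48 and 0.52 in that order. In each of these 4 lists 0 members passed over all genes, with 4, 3, 4 and 1 at an unadjusted p under 0.05 and 0, 1, 2 and 0 adjusted over the list alone.

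Lists that did not pass in this comparison included amino acid transporters (adjusted p = 0.762), tuft cells (0.071), tight and adherens junctions (0.071), the small intestine (0.796), posterior Hox genes (0.711), glucocorticoid targets (0.57), the circadian clock (0.181), and the genes beside Lao1 (0.904) and beside Il4i1 (0.793). Of the clock genes Arntl alone passed over all genes, and adjusted over the list alone 5 were higher (Ciart 1.64, Per2 1.54, Dbp 1.37, Per3 1.35, Per1 0.98) and 3 lower (Arntl -2.48, Npas2 -2.24, Nr1d1 -1.08). In all, 16 of 40 lists passed camera, 7 higher and 9 lower; with an estimated correlation 0 passed (3 at an unadjusted p under 0.05) and with fry 1 did. Over all 6 comparisons, the camera calls that held with an estimated correlation were the interferon response in the double knockout against either single knockout and in the interaction, and the enteroendocrine list in the double knockout against the IL4i1 knockout and in the interaction. Median, mean and test differed in sign for amino acid transporters (median -0.16, mean 0.05, test lower) and the small intestine (0.14, -0.04, test higher), both not past.

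Some of these calls ended when 1 array was left out. Here and later, where a test failed, the adjusted p without it follows, as a range for genes and in array order for lists tested with camera, with knockout arrays named by the loss. Arntl failed without wild type replicates 1 and 2 or double replicates 1 and 3 (0.0783 to 0.165). Hao2 failed without wild type replicate 2 (0.061). Nupr1 failed without wild type replicates 2 and 3 or double replicates 1 and 3 (0.0661 to 0.155). Sulf2 failed without wild type replicates 1, 2 and 3 or double replicates 1 and 3 (0.0526 to 0.153). ATF4 targets failed without wild type replicate 3 or double replicates 1 and 2 (0.189, 0.0616 and 0.327). PPAR targets failed without wild type replicate 2 or double replicates 2 and 3 (0.0544, 0.0503 and 0.0604). T and innate lymphoid cells failed without wild type replicates 2 and 3 or double replicates 2 and 3 (0.092, 0.0707, 0.0808 and 0.25). Absorptive colonocytes failed without wild type replicate 2 or double replicates 1 and 2 (0.111, 0.0616 and 0.0503). Adipocytes failed without wild type replicate 3 (0.0707). Endothelial cells failed without wild type replicate 1 or double replicate 3 (0.0716 and 0.412). Enteroendocrine genes failed without wild type replicate 1 (0.0715). Goblet cells failed without double replicate 1 (0.42). Immediate early and heat shock genes failed without wild type replicate 2 (0.092). Ion and water transport genes failed without wild type replicate 1 or double replicates 1 and 2 (0.0648, 0.0859 and 0.0503). Calls held, with means moved over 1.5 times, for inflammatory genes 0.23 (adjusted p = 0.0384), acinar genes 4.21 and proliferation 0.18 without double replicate 1; ATF4 targets 0.55 and acinar genes 3.88 without double replicate 3. Over bright probes (above the 40th percentile) the enteroendocrine, T cell and acinar lists failed.

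In the LAO1 knockout against wild type, Sh3d19 rose 7.6-fold (log2 2.93, SE 0.19, adjusted p = 1.81e-05), with 3 of 3 arrays above all wild type arrays. It was the only probe past limma's threshold, while 670 had an unadjusted p under 0.05. The mucosal mast cell protease Mcpt1 was at 7.42 ± 0.68 against 11.19 ± 1.35 (SD, n = 3), a difference of -3.77 that did not pass (SE 0.6, adjusted p = 0.282). Other genes next in order of p were Mcpt2 (-2.57) and Rhbdl2 (-1.63; both 0.84), and Osmr (-1.29), Zbtb14 (0.88) and Olfr1443 (1.01; each 0.88). Without LAO1 knockout replicate 1 the count was 4, and without wild type replicate 2 it was 2.

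Interferon response genes stood lower as a list in the LAO1 knockout, with a mean difference of -0.64 (camera, adjusted p = 2.71e-14, adjusted p = 0.237 with an estimated correlation). Over all genes 0 of 31 members passed, 11 had an unadjusted p under 0.05, all lower, and 3 passed adjusted over the list alone, Irgm2 (-2.1), Gbp7 (-1.41) and Oasl2 (-1.15). MHC class II genes stood at -0.44 (adjusted p = 0.00362, adjusted p = 0.907 with an estimated correlation), with H2-Eb1 (-1.11) past adjusted over the list alone. Mast cell and eosinophil markers stood at -0.65 (adjusted p = 0.000448, adjusted p = 0.438 with an estimated correlation), with Mcpt1, Mcpt2 and the protease Cpa3 (-1.85) past adjusted over the list alone, 3 of 15 members against 0 over all genes and 4 at an unadjusted p under 0.05. Macrophage, monocyte and dendritic cell markers followed at -0.25 (adjusted p = 0.00472, adjusted p = 0.82 with an estimated correlation; Ccr2 -0.7).

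Immediate early and heat shock genes stood at -0.91 (adjusted p = 4.88e-11, adjusted p = 0.237 with an estimated correlation). Hspa1b (-2.69), Hspa1a (-2.31) and Nr4a1 (-1.36) passed adjusted over the list alone, 3 of 20 members against 0 over all genes and 6 at an unadjusted p under 0.05. Hspa1b was at 12.79 in wild type replicate 2. Adipocyte genes stood at -0.58 (adjusted p = 0.000143; Adipoq -0.86), fibroblast and matrix genes at -0.32 (0.00507; Mgp -0.72) and smooth muscle at -0.26 (0.046; Synm -0.69). In that order the adjusted p with an estimated correlation was 0.348, 0.907 and 0.963. B cell genes stood 0.35 higher (0.00507, adjusted p = 0.907 with an estimated correlation; Bank1 0.97), with all 15 members positive. In these 4 lists and the macrophage list 0 members passed over all genes or adjusted over the list alone, and 1, 1, 0, 0 and 3 had an unadjusted p under 0.05. Of 40 lists 9 passed camera, 1 higher and 8 lower, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 0 with fry (3). Median, mean and test differed in sign in 0 of the 9 and in 5 of the other lists.

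In the LAO1 knockout comparison 5 list calls ended when 1 array was left out. B cells failed without wild type replicate 2 or LAO1 replicate 1 (0.1 and 0.903, the last at a mean of -0.01). MHC class II genes failed without wild type replicate 3 or LAO1 replicate 2 (0.0564 and 0.417). Fibroblasts failed without wild type replicates 1 and 2 (0.0617 and 0.274). Macrophages and monocytes failed without wild type replicate 1 or LAO1 replicate 2 (0.35 and 0.134). Smooth muscle genes failed without wild type replicates 2 and 3 or LAO1 replicate 1 (0.569, 0.197 and 0.903, the last at a mean of 0.03). Calls held, with means moved over 1.5 times, for smooth muscle -0.41 without wild type replicate 1; immediate early genes -0.55 without wild type replicate 2; fibroblasts -0.52 and macrophages -0.4 without wild type replicate 3; MHC class II -0.76 without LAO1 replicate 1; B cells 0.7 and smooth muscle -0.46 without LAO1 replicate 2. Over bright probes B cells and smooth muscle failed, and smooth muscle did with quantile normalization.

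In the IL4i1 knockout against wild type 2 mast cell proteases fell. Mcpt1 fell by 7.82 on the log2 scale (SE 0.6, adjusted p = 6.75e-05), from 11.19 ± 1.35 to 3.36 ± 0.54. Mcpt2 fell by 3.74 (SE 0.5, adjusted p = 0.0317), from 7.09 ± 1.24 to 3.35 ± 0.21. Both low levels lay under the lower quartile of every array (3.64 to 3.88), so the sizes are uncertain. Sh3d19 rose 10.3-fold (log2 3.37, SE 0.19, adjusted p = 3.04e-06). For these 3 genes all 3 knockout arrays lay beyond all 3 wild type arrays (SD, n = 3).

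They were the only probes past limma's threshold, against 1684 at an unadjusted p under 0.05. Not past it stood Fam83e (1.33, adjusted p = 0.0689), the mast cell protease Cpa3 (-2.7, to a low level of 3.69), the T cell checkpoint ligand Cd274 (-1.87), the plasminogen activator Plau (-2.18) and Csta1 (1.22; each 0.0709), and the clock output gene Dbp (2.08) and Fam161a (0.99; both 0.122). The count was 2 without wild type replicate 3 or any IL4i1 knockout array and 5 without wild type replicate 2, and 6 without double knockout replicate 1.

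Mast cell and eosinophil markers shifted lower as a list, by a mean of -1.2 over 15 members (camera, adjusted p = 1.37e-05, adjusted p = 0.284 with an estimated correlation). Mcpt1 and Mcpt2 fell over all genes, 13 did not pass, and adjusted over the list alone Cpa3 and Il5ra (-1.64) joined them for 4. The interferon response stood at -0.92 (adjusted p = 9.56e-17, adjusted p = 0.161 with an estimated correlation), with 0 of 31 members past over all genes, 16 at an unadjusted p under 0.05 and 13 adjusted over the list alone, among them Iigp1 (-3.09), Irgm2 (-2.96) and Tap1 (-2.07). MHC class II genes stood at -0.61 (adjusted p = 0.00548, adjusted p = 0.704 with an estimated correlation), and H2-Aa (-1.47), H2-Ab1 (-1.37) and H2-Eb1 (-1.34) passed adjusted over the list alone, against 0 over all genes and 4 at an unadjusted p under 0.05. Macrophage, monocyte and dendritic cell markers stood at -0.55 (adjusted p = 1.26e-05, adjusted p = 0.284 with an estimated correlation; Csf1r -1.38 and C1qa -1.05), with 0 of 23 past over all genes or adjusted over the list alone and 8 at an unadjusted p under 0.05.

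Cholesterol synthesis genes stood at -0.56, with all 17 measured members negative (adjusted p = 1.22e-05, adjusted p = 0.643 with an estimated correlation) and Cyp51 (-1.52), Stard4 (-1.2) and Fdps (-0.89) past adjusted over the list alone. Stem cell and proliferation genes stood at -0.33 (adjusted p = 0.036; Mki67 -1.66), ATF4 targets at -0.35 (0.0376; asparagine synthetase Asns -1.18), fibroblast and matrix genes at -0.39 (0.0151; Col1a2 -1.25) and immediate early and heat shock genes at -0.66 (0.00158; Hspa1b -2.96). The adjusted p with an estimated correlation was 0.704, 0.704, 0.704 and 0.643 in that order. Plasma cell genes stood at -0.81 (0.0047, adjusted p = 0.704 with an estimated correlation), with Jchain at 12.5 in IL4i1 knockout replicate 2 and at 17.71 and 18.18 in the other arrays of that genotype. Enteroendocrine genes stood 0.45 higher (adjusted p = 0.00446; Tac1 1.55 and Scg2 0.75), smooth muscle 0.28 higher (0.0429; Lmod1 0.62) and B cells 0.32 higher (0.0311; Bank1 1.04). Their adjusted p with an estimated correlation was 0.162, 0.704 and 0.704 in that order. The circadian clock stood 0.32 higher (0.0151, adjusted p = 0.643 with an estimated correlation), with Dbp, Per2 (1.23), Per3 (1.23) and Ciart (1.1) higher and Arntl (-1.48) lower adjusted over the list alone.

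Over all genes 0 members of these 10 lists passed limma's test. In the order given, from cholesterol synthesis to the clock, 5, 5, 4, 1, 3, 1, 2, 0, 0 and 6 had an unadjusted p under 0.05. Adjusted over the list alone the 3 cholesterol genes, Hspa1b and the 5 clock genes passed, and 0 in the other 7 lists. Of 40 lists 14 passed camera, 4 higher and 10 lower, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 0 with fry (5). Median, mean and test differed in sign in 0 of the 14 and in 8 of the others.

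Without 1 array, calls of the IL4i1 knockout ended as well. Mcpt2 failed without wild type replicate 3 or IL4i1 replicates 1, 2 and 3 (0.109 to 0.181). ATF4 targets failed without wild type replicates 1 and 2 or IL4i1 replicates 1 and 3 (0.071, 0.156, 0.186 and 0.0965). B cells failed without wild type replicates 2 and 3 or IL4i1 replicate 1 (0.156, 0.124 and 0.966, the last at a mean of -0.09). MHC class II genes failed without wild type replicate 3 or IL4i1 replicate 2 (0.0607 and 0.169). Circadian clock genes failed without wild type replicate 3 or IL4i1 replicates 1 and 3 (0.339, 0.165 and 0.0814). Fibroblasts failed without wild type replicates 1 and 2 or IL4i1 replicate 2 (0.0564, 0.236 and 0.326). Immediate early and heat shock genes failed without wild type replicate 2 or IL4i1 replicate 1 (0.0656 and 0.114). Plasma cells failed without wild type replicate 1 or IL4i1 replicate 2 (0.133 and 0.203). Smooth muscle genes failed without wild type replicates 1 and 3, IL4i1 replicates 2 and 3 or double replicate 1 (0.386, 0.129, 0.883, 0.194 and 0.0508). Proliferation genes failed without wild type replicate 1 or IL4i1 replicate 3 (0.31 and 0.103). Calls held, with means moved over 1.5 times, for cholesterol synthesis -0.36 without wild type replicate 1; fibroblasts -0.59 without wild type replicate 3; MHC class II -1 and smooth muscle 0.61 without IL4i1 replicate 1; B cells 0.61 and cholesterol synthesis -0.32 without IL4i1 replicate 2. With quantile normalization ATF4 targets, proliferation, B cells and fibroblasts failed, and over bright probes ATF4 targets, proliferation and B cells.

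The effects of the single deletions against wild type correlated at r = 0.513 across 22206 probes, which are not independent replicates. Unchanged groups simulated against shared wild type arrays gave 0.499 (SD 0.0122), and the covariance was 0.056 against a simulated 0.046, a difference of 0.009. Of the calls, Sh3d19 was shared, 1 of 1 higher call in each, against 4.5e-05 for independent lists. Part of any excess may come from the shared wild type arrays, which were too few to split into groups of 2. Without wild type replicates 1, 2 and 3 in turn the correlation was 0.535, 0.523 and 0.685, against 0.602, 0.6 and 0.601 simulated with the other 2 shared.

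In the double knockout against the LAO1 knockout, 9 of 31 measured interferon response genes rose. Iigp1, an immunity-related GTPase that attacks the vacuoles of intracellular microbes, rose 70.2-fold, from 4.88 ± 0.39 to 11.02 ± 1.26. Igtp rose 24.9-fold and Gbp2 22-fold, and the peptide transporter Tap1 by 3.55 on the log2 scale. Mcpt1 rose 39.2-fold, from 7.42 ± 0.68 to 12.71 ± 0.85, and Mcpt2 from a low 4.52 to 7.97. Nupr1 (log2 -3.56), Hao2 (-2.31), the clock repressor Nr1d1 (-1.89) and the sulfotransferase Sult1c2 (-1.81) fell (SD, n = 3).

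Limma passed 31 probes, 27 higher and 4 lower, of which 27 were named. The adjusted p was 0.0114 for Iigp1 (log2 6.13, SE 0.9), 0.0041 for Igtp (4.64), Irgm2 (4.23), Gm12250 (4.15), Mcpt1 (5.29, SE 0.6), Gbp3 (2.76), Gbp7 (3.14), Oasl2 (2.52) and Hao2, 0.00867 for Gbp2 (4.46) and Nupr1, 0.00463 for Gm4841 (6.01), 0.00916 for Tgtp2 (5.72), 0.0101 for Tap1, 0.0111 for Mcpt2 (3.46), 0.0114 for Nr1d1 and 0.0218 for Sult1c2. In all 19 genes the rule named as past the threshold the 3 double knockout arrays lay beyond the 3 of the LAO1 knockout. Iigp1, Gm4841, Gm12250, Tgtp2, Igtp and Irgm2 belong to 1 gene family, and probes of close relatives may share signal. The count was 15 and 11 without LAO1 knockout replicates 2 and 3, 13 and 14 without double knockout replicates 1 and 3, and 68 without double knockout replicate 2. In all traced runs 9 of these 19 genes passed.

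Of 31 measured interferon response genes 9 rose, 0 fell and 22 did not pass, and 24 were higher adjusted over the list alone. The list mean rose by 1.76 (camera, adjusted p = 2.35e-40, 0.0104 as the adjusted p with an estimated correlation, 0.0011 with fry), with 3 of 3 arrays above. Of 10 MHC class II genes H2-Ab1 (2.27, adjusted p = 0.0395) and H2-Eb1 (2.13, 0.00737) rose and 8 did not pass, among them H2-Aa (2.35, 0.094), with 6 higher adjusted over the list alone. That list stood 1.46 higher (adjusted p = 1.49e-11, adjusted p = 0.298 with an estimated correlation). In the mast cell list Mcpt1 and Mcpt2 rose, 13 did not pass, and Cpa3 (1.88) and Ms4a2 (1.01) joined them adjusted over the list alone, 4 in all; the list mean was 0.75 (adjusted p = 0.000967, adjusted p = 0.371 with an estimated correlation). Inflammatory genes stood 0.67 higher (adjusted p = 5.62e-06, adjusted p = 0.371 with an estimated correlation), with Cxcl9 (4.89), Ccl8 (2.47), Cxcl10 (1.78) and Ifng (1.23) past adjusted over the list alone, against 0 over all genes and 12 at an unadjusted p under 0.05.

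Ido1 stood 7.06 above the LAO1 knockout (adjusted p = 0.073), past adjusted over the list alone; it was named from here on after its values were seen. T and innate lymphoid cell markers stood 0.34 higher (adjusted p = 0.000967; Gzmb 1.14 and Cd3e 0.86), macrophage, monocyte and dendritic cell markers 0.33 (0.00211; Aif1 1.08), neutrophil genes 0.31 (0.0286; Csf3r 0.78), stem cell and proliferation genes 0.56 (6.02e-07; Rrm2 1.22), immediate early and heat shock genes 0.24 (0.0479; Junb 1.03) and ATF4 targets 0.32 (0.0136; Phgdh 1.27 and Shmt2 1.26). With an estimated correlation the adjusted p was 0.371, 0.375, 0.441, 0.371, 0.741 and 0.441 in that order. Acinar genes stood 2.33 higher (0.0125, adjusted p = 0.741 with an estimated correlation) and at -0.62 (adjusted p = 0.0304) without double knockout replicate 2.

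Goblet cell genes stood lower, by a mean of -0.52 (adjusted p = 4.46e-05; the trefoil peptide Tff3 -1.35), enteroendocrine genes at -0.39 (0.00211; Gcg -0.87) and absorptive colonocyte genes at -0.57 (0.0138; Ceacam20 -2.15). In that order the adjusted p with an estimated correlation was 0.371, 0.135 and 0.441. In these 10 lists 0 members passed over all genes except Nupr1, which fell. In the order given, from T cells to absorptive colonocytes, 6, 4, 1, 5, 1, 6, 0, 4, 2 and 4 had an unadjusted p under 0.05. Adjusted over the list alone 2 of the T cell list and 2 of the ATF4 list were higher, and Nupr1 and Ceacam20 lower. Of 40 lists 14 passed camera, 11 higher and 3 lower, 1 with an estimated correlation and 1 with fry. Median, mean and test differed in sign in 0 of the 14 and in 7 of the others.

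Calls against the LAO1 knockout also ended without 1 array. Gbp2 failed without LAO1 replicate 3 or double replicates 1 and 3 (0.0508 to 0.068). H2-Ab1, H2-Eb1, Nr1d1, Nupr1, Tap1 and Tgtp2 failed without LAO1 replicates 2 and 3 or double replicates 1 and 3 (0.0508 to 0.182). Iigp1 failed without LAO1 replicates 1, 2 and 3 or double replicates 1 and 3 (0.0515 to 0.0984). Mcpt2 failed without LAO1 replicates 1 and 2 or double replicate 3 (0.0619 to 0.0766). Sult1c2 failed without LAO1 replicates 1, 2 and 3 or double replicates 2 and 3 (0.0546 to 0.128). ATF4 targets failed without LAO1 replicate 1 or double replicate 2 (0.0625 and 0.243). Immediate early and heat shock genes failed without LAO1 replicates 1 and 2 or double replicates 2 and 3 (0.151, 0.118, 0.2 and 0.111). Macrophages and mast cells failed without double replicate 2 (0.0983 and 0.0736). Neutrophils failed without LAO1 replicates 1 and 2 or double replicate 1 (0.0607, 0.122 and 0.501). Calls held, with means moved over 1.5 times, for ATF4 targets 0.19, goblet cells -0.33, inflammatory genes 0.22, acinar genes 3.97 and proliferation 0.23 without double replicate 1; ATF4 targets 0.61 and acinar genes 3.64 without double replicate 3. Iigp1 and Tgtp2 failed with the trend and robust options, and neutrophils and acinar genes over bright probes.

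In the double knockout against the IL4i1 knockout, Mcpt1 rose from 3.36 ± 0.54 to 12.71 ± 0.85. The lower mean lay under the lower quartile of every array, so no fold is given. Tgtp2 rose 107-fold, and Iigp1 and Igtp rose from low levels, 4.47 and 4.65, to 11.02 and 9.35. Upp1, a uridine phosphorylase, was at 9.28 ± 2.36 against 4.69 ± 0.35. The tight junction protein Cldn8 fell by 3.08 on the log2 scale, from 7.17 ± 1.13 to 4.08 ± 0.38, and the magnesium channel Trpm6 fell by 2.54, from 7.96 ± 0.82 to 5.42 ± 0.21. Hao2, Nupr1, Nr1d1 and Sult1c2, lower against the LAO1 knockout too, also fell (log2 -2.51, -2.64, -1.8 and -2.79; SD, n = 3).

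Limma passed 106 probes, 86 higher and 20 lower, of which 92 were named. The log2 difference of Mcpt1, whose size is uncertain, was 9.35 (SE 0.6, adjusted p = 1.47e-05). Further rises were Iigp1 (6.55, adjusted p = 0.0045), Tgtp2 (6.74) and Igtp (4.7; both 0.0014), Gm4841 (6.13, 0.00168), Irgm2 (5.1) and Gm12250 (4.84; both 0.000701), Mcpt2 (4.63, 0.000882, likewise uncertain), Upp1 (4.59, SE 0.8, 0.0219) and Tap1 (4.41, 0.00127). Falls included Rhbdl2 (-3.04, 0.000701), Cldn8 (-3.08, 0.0149), Nt5c1a (-2.76) and Wfdc2 (-2.15; both 0.00928), Trpm6 (-2.54, 0.0161) and the noncoding transcript Ipw (-2.39, 0.0166). In all 31 genes the rule named as past the threshold the 3 arrays of the double knockout lay beyond the 3 of the IL4i1 knockout. Without double knockout replicates 1 and 2 the count was 46 and 174, without IL4i1 knockout replicates 2 and 3 it was 51 and 61, and in a fit to the 6 arrays alone 33. In all traced runs 19 of these 31 genes passed.

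Of the interferon response genes 15 of 31 rose, 0 fell and 16 did not pass, and 25 were higher adjusted over the list alone. The list mean rose by 2.04 (adjusted p = 1.61e-40, 0.00933 as the adjusted p with an estimated correlation, 0.000386 with fry). Of the MHC class II genes H2-Aa (2.98, adjusted p = 0.012), H2-DMb1 (2.83, 0.0412), H2-Ab1 (2.72, 0.00578) and H2-Eb1 (2.36, 0.00147) rose and 6 did not pass, with 6 higher adjusted over the list alone; the list stood 1.63 higher (adjusted p = 8.5e-10, adjusted p = 0.252 with an estimated correlation). Mcpt1, Mcpt2 and Cpa3 (2.72, 0.0115, from a low 3.69) rose in the mast cell list, 12 did not pass, and the same count of 3 passed adjusted over the list alone; its mean was 1.3 (adjusted p = 7.35e-06, adjusted p = 0.229 with an estimated correlation, 0.0223 with fry). In the inflammatory list the chemokine Ccl8 rose (3.39, 0.018) and 35 did not pass, and adjusted over the list alone 3 were higher, with Cxcl9 (5.52) and Cxcl10 (1.8), and 2 lower, Il18 (-2.95) and Saa1 (-2.45); the list stood 0.52 higher (0.00271, adjusted p = 0.468 with an estimated correlation).

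Enteroendocrine genes fell as a list by a mean of 0.75 over 18 members (adjusted p = 2.69e-07, 0.00933 as the adjusted p with an estimated correlation, 0.00351 with fry), with 3 of 3 arrays below. Over all genes 0 passed in limma's test, 7 had an unadjusted p under 0.05, and 6 were lower adjusted over the list alone, among them the granins Chgb (-1.94) and Chga (-1.45), the secretogranin Scg2 (-1.2) and somatostatin, Sst (-1.1). The list mean was 5.91 ± 0.07 in the double knockout, 6.66 ± 0.08 in the IL4i1 knockout, 6.3 ± 0.17 in the LAO1 knockout and 6.21 ± 0.23 in wild type (SD, n = 3). Chgb, Chga, Scg2 and Sst are known from enteric neurons too, whose list, with 3 of 3 arrays below, stood at -0.37, and smooth muscle at -0.73.

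Among ATF4 targets Asns (1.87, adjusted p = 0.0348) and the folate enzyme Mthfd2 (1.75, 0.0425) rose, Nupr1 fell and 16 did not pass, with 6 higher and 1 lower adjusted over the list alone. That list stood 0.6 higher (adjusted p = 0.000133, adjusted p = 0.26 with an estimated correlation). Stem cell and proliferation genes stood 0.84 higher (1.27e-10, adjusted p = 0.252 with an estimated correlation), with 0 of 23 past over all genes, 14 at an unadjusted p under 0.05 and 12 adjusted over the list alone, such as Top2a (1.55), Plk1 (1.55) and Rrm2 (1.49). Macrophage, monocyte and dendritic cell markers stood 0.63 higher (1.41e-06, adjusted p = 0.229 with an estimated correlation), with 5 of 23 past adjusted over the list alone, among them the monocyte marker Ly6c2 (2.85) and complement C1qa (1.28), 0 over all genes and 8 at an unadjusted p under 0.05. T and innate lymphoid cell markers stood 0.3 higher (adjusted p = 0.00894; Gzma 1.52 and Gzmb 1.04), plasma cell genes 0.64 (0.0325; Mzb1 1.52) and antimicrobial proteins 0.84 (0.0466; Retnlb 1.53). The adjusted p with an estimated correlation was 0.3, 0.553 and 0.3 in that order.

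Cholesterol synthesis genes stood 0.65 higher with all 17 members positive (adjusted p = 7.43e-08; Fdps 0.98), hydrogen peroxide and superoxide enzymes 0.29 (0.0182; the superoxide-producing oxidase Nox1 1.33) and oxidative phosphorylation 0.19 (0.0258; Sdhc 0.64). Their adjusted p with an estimated correlation was 0.3, 0.387 and 0.689 in that order. Acinar genes stood 2.52 higher (0.00293, adjusted p = 0.561 with an estimated correlation) and at -0.42 (adjusted p = 0.0942) without double knockout replicate 2. Smooth muscle stood at -0.73 (adjusted p = 5.34e-07; Mylk -1.28), absorptive colonocytes at -0.78 (0.000477; Ceacam20 -1.68), enteric neurons and glia at -0.37 (0.000619; Snap25 -0.98) and bile acid and xenobiotic metabolism at -0.65 (0.00431; Gsta4 -1.06). With an estimated correlation the adjusted p was 0.35, 0.26, 0.3 and 0.382 in that order. In the 11 lists from the T cell list on, 0 members passed over all genes, and in the order given 3, 1, 1, 8, 6, 1, 0, 6, 5, 3 and 5 had an unadjusted p under 0.05. Adjusted over the list alone Gzma and Gzmb were higher, and 4 smooth muscle genes, Ceacam20, Saa1, Snap25 and Gsta4 lower.

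Among lists that did not pass, Cldn8 was the 1 member of 20 tight and adherens junction genes past the threshold over all genes, and it fell (list adjusted p = 0.194). Ido1 stood 6.59 above the IL4i1 knockout (adjusted p = 0.0523), past adjusted over the list alone. Of 40 lists 19 passed camera, 14 higher and 5 lower, 2 with an estimated correlation and 3 with fry. Median, mean and test differed in sign in 0 of the 19 and in 7 of the others.

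Against the IL4i1 knockout, calls ended without 1 array too. Asns and Mthfd2 failed without IL4i1 replicates 1, 2 and 3 or double replicates 1 and 2 (0.0533 to 0.19). Ccl8 failed without IL4i1 replicates 2 and 3 or double replicate 3 (0.0671 to 0.0941). Cldn8 failed without double replicate 1 (0.0857). H2-Aa failed without double replicates 1 and 3 (0.0562 to 0.0586). H2-DMb1 failed without IL4i1 replicates 2 and 3 or double replicates 1 and 3 (0.125 to 0.19). Ipw failed without IL4i1 replicates 1 and 2 or double replicate 1 (0.0518 to 0.102). Nr1d1 failed without IL4i1 replicate 3 (0.052). Nt5c1a failed without IL4i1 replicate 2 or double replicate 1 (0.0501 to 0.0533). Nupr1 failed without IL4i1 replicates 1 and 2 or double replicates 1, 2 and 3 (0.0546 to 0.156). Trpm6 failed without IL4i1 replicates 1 and 3 or double replicates 1 and 3 (0.0518 to 0.0675). Upp1 failed without IL4i1 replicates 1, 2 and 3 or double replicates 1 and 3 (0.0658 to 0.12). T and innate lymphoid cells failed without double replicate 3 (0.0955). Absorptive colonocytes failed without IL4i1 replicate 2 (0.0736). Antimicrobial proteins failed without IL4i1 replicates 1 and 2 or double replicate 1 (0.214, 0.135 and 0.72). Bile acid metabolism genes failed without IL4i1 replicate 1 (0.148). Hydrogen peroxide enzymes failed without IL4i1 replicate 3 or double replicate 1 (0.0563 and 0.552). Inflammatory genes failed without IL4i1 replicate 1 or double replicate 1 (0.0563 and 0.754). Oxidative phosphorylation genes failed without IL4i1 replicates 1 and 3 or double replicates 1 and 3 (0.276, 0.526, 0.108 and 0.516). Plasma cells failed without IL4i1 replicate 2 or double replicates 2 and 3 (0.583, 0.376 and 0.0803). Calls held, with means moved over 1.5 times, for cholesterol synthesis 0.41, oxidative phosphorylation 0.42 and smooth muscle -0.47 without IL4i1 replicate 2; absorptive colonocytes -1.23 and bile acid metabolism -1.14 without IL4i1 replicate 3; acinar genes 4.16, plasma cells 0.97 and proliferation 0.51 without double replicate 1; inflammatory genes 0.81 and oxidative phosphorylation 0.37 without double replicate 2; acinar genes 3.83 without double replicate 3. Upp1 failed with the trend and robust options, antimicrobial proteins with median centring, and these, hydrogen peroxide enzymes and oxidative phosphorylation with quantile normalization and over bright probes, where inflammatory, plasma cell and acinar genes failed too.

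The differences of the double knockout from the single knockouts shared 26 higher calls, of 27 and 86, and 4 lower ones, of 4 and 20, against 0.105 and 0.0036 for independent lists. Their log2 differences correlated at r = 0.707 across probes, against 0.499 simulated for unchanged groups, with a covariance of 0.134 against 0.046, a difference of 0.087. Part of the excess may come from the shared double knockout arrays.

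**Figure D2:**
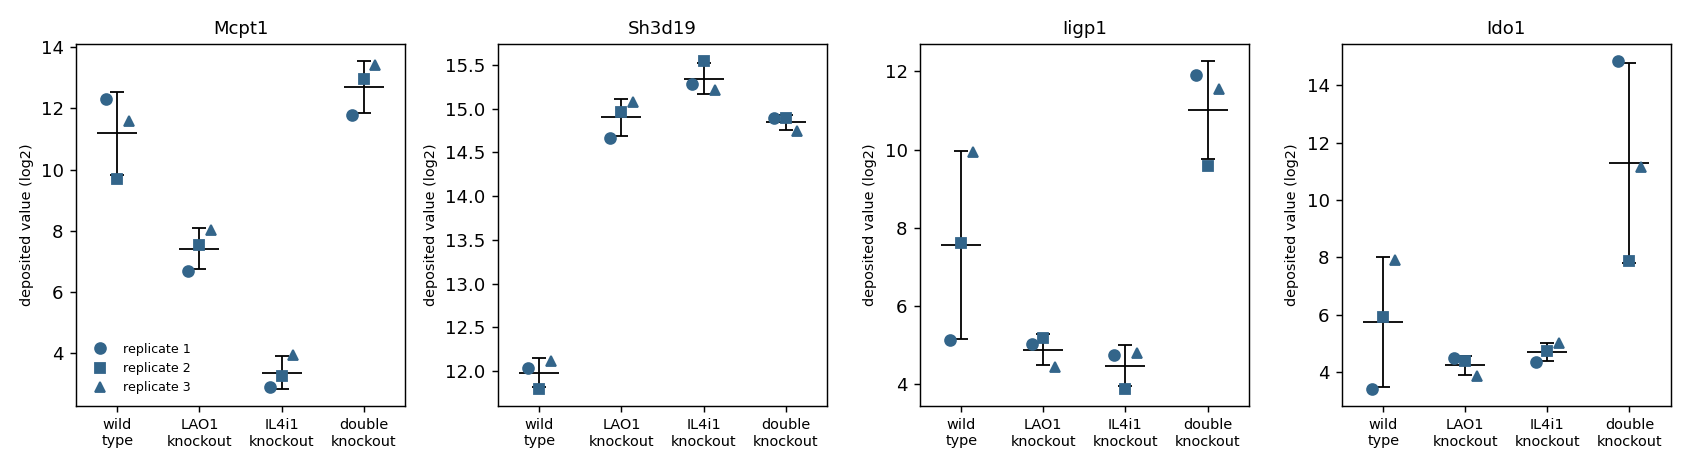
Log2 value of Mcpt1, Sh3d19, Iigp1 and Ido1 (vertical axis, log2) in the 4 genotypes (horizontal axis), with points for the 12 arrays and bars for the group mean and SD. Mcpt1 was at 11.77 to 13.41 in the double knockout and 2.88 to 3.95 in the IL4i1 knockout, and Sh3d19 was at 11.79 to 12.11 in wild type and 14.67 to 15.55 in all knockout arrays.

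The interaction asked whether the loss of both genes differed from the sum of the single losses on the log2 scale. Mcpt1 departed by 13.12 (SE 0.85, adjusted p = 1.62e-05), with means of 11.19 in wild type, 7.42 in the LAO1 knockout, 3.36 in the IL4i1 knockout and 12.71 ± 0.85 in the double knockout (SD, n = 3). Its size is uncertain, as 3.36 lay near the bottom of the range. Of 31 interferon response genes 12 stood above the sum, with Iigp1 at 9.22 (SE 1.27, adjusted p = 0.00599), Irgm2 at 7.2 and Igtp at 6.24. Sh3d19 departed downward, by -3.43 (SE 0.27, adjusted p = 9.47e-05). Hao2 (-2.44), Nr1d1 (-2.6), Sult1c2 (-2.69) and Fam161a (-1.54) were the other named genes below the sum.

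Limma passed 51 probes, 46 above and 5 below the sum, with 46 named. Further genes above the sum were Tgtp2 (8.8), Gm4841 (8.6), Mcpt2 (7.2), Gm12250 (6.13), Gbp2 (5.79), Tap1 (5.62), Gbp7 (4.62), Ccl8 (4.67), Cpa3 (4.57), Gbp3 (4.08), H2-Aa (3.82), Oasl2 (3.81), H2-Ab1 (3.64) and H2-Eb1 (3.47), with adjusted p from 0.000953 for Mcpt2 to 0.0337 for Ccl8. The sizes for Mcpt2 and Cpa3 are uncertain, as their IL4i1 knockout levels were 3.35 and 3.69. Ido1 stood 8.11 above the sum (adjusted p = 0.18), past adjusted over the list alone. In the traced runs 18 of the 23 genes the rule named always passed, and Iigp1 failed only with trend and robust options.

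The interferon response list stood 2.68 above the sum (camera, adjusted p = 2.59e-46, 0.00645 as the adjusted p with an estimated correlation, 0.000601 with fry), with 12 of 31 members above it, 0 below and 23 past adjusted over the list alone. MHC class II genes stood 2.06 above (adjusted p = 4.03e-10, adjusted p = 0.238 with an estimated correlation), with 3 of 10 members past over all genes and 6 adjusted over the list alone. Mast cell markers stood 1.95 above (4.76e-07, adjusted p = 0.131 with an estimated correlation, 0.0156 with fry), with 3 of 15 members past over all genes and 4 adjusted over the list alone. Enteroendocrine genes stood at -0.84 (1.14e-05, 0.0233 as the adjusted p with an estimated correlation, 0.0156 with fry), with 0 of 18 past over all genes, 7 at an unadjusted p under 0.05 and Scg2 (-1.5) past adjusted over the list alone. Macrophage, monocyte and dendritic cell markers stood 0.88 above (adjusted p = 5.49e-08; Ccr2 1.86), stem cell and proliferation genes 0.89 (2.21e-07; Mki67 2.42), immediate early and heat shock genes 0.9 (3.7e-05; Fos 1.85), ATF4 targets 0.67 (0.00176; Asns 1.92) and cholesterol synthesis 0.56 (0.000552; Cyp51 1.32). In that order the adjusted p with an estimated correlation was 0.131, 0.367, 0.367, 0.367 and 0.681.

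T and innate lymphoid cell markers stood 0.39 above the sum (adjusted p = 0.00412; Gzmb 1.65), inflammatory genes 0.51 (0.0307) and fibroblast and matrix genes 0.47 (0.0207; Fn1 1.03). The adjusted p with an estimated correlation was 0.367, 0.695 and 0.695 in that order. Below it stood absorptive colonocytes at -0.67 (adjusted p = 0.00966; Saa1 -3.81), smooth muscle at -0.48 (0.0102; Acta2 -0.78), bile acid and xenobiotic metabolism at -0.74 (0.0142; Gsta4 -1.17) and B cells at -0.5 (0.0288; Bank1 -1.76). Their adjusted p with an estimated correlation was 0.451, 0.695, 0.681 and 0.695 in that order. In the 12 lists from the macrophage list on, Ccl8 was the only member past over all genes, and in the order given 8, 10, 3, 7, 0, 3, 7, 1, 3, 1, 3 and 0 had an unadjusted p under 0.05. Adjusted over the list alone 3 macrophage genes, 3 proliferation genes, Asns, Mthfd2, Gzmb, Ccl8 and Cxcl9 stood above and Nupr1, Saa1 and Saa2 below. Of 40 lists 16 passed camera, 11 above and 5 below, 2 with an estimated correlation and 3 with fry. Median, mean and test differed in sign in 0 of the 16 and in 4 of the others.

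Interaction calls also ended without 1 array. Ccl8 failed without wild type replicates 1 and 2, LAO1 replicates 2 and 3, IL4i1 replicates 2 and 3 or double replicates 2 and 3 (0.0555 to 0.13). Fam161a failed without wild type replicate 1, LAO1 replicate 2, IL4i1 replicate 3 or double replicate 1 (0.0535 to 0.0661). H2-Aa failed without wild type replicates 1, 2 and 3, LAO1 replicates 2 and 3, IL4i1 replicates 2 and 3 or double replicates 1 and 3 (0.0533 to 0.104). Hao2 failed without wild type replicates 1 and 2, LAO1 replicates 1, 2 and 3 or IL4i1 replicate 2 (0.0505 to 0.069). B cells failed without wild type replicates 2 and 3, LAO1 replicate 1, IL4i1 replicate 1 or double replicate 1 (0.0984, 0.071, 0.545, 0.702 and 0.251). Absorptive colonocytes failed without wild type replicate 3 or IL4i1 replicate 2 (0.0648 and 0.235). Bile acid metabolism genes failed without wild type replicate 1, LAO1 replicate 2, IL4i1 replicates 1 and 2 or double replicate 3 (0.0569, 0.181, 0.162, 0.0699 and 0.0569). Fibroblasts failed without wild type replicates 1 and 2, IL4i1 replicate 2 or double replicates 1 and 2 (0.0549, 0.144, 0.248, 0.137 and 0.466). Inflammatory genes failed without wild type replicate 3, LAO1 replicate 2, IL4i1 replicate 1 or double replicate 1 (0.173, 0.126, 0.175 and 0.745). Smooth muscle genes failed without wild type replicate 1, LAO1 replicate 2, IL4i1 replicate 2 or double replicates 1 and 3 (0.0773, 0.181, 0.268, 0.072 and 0.0709). Calls held, with means moved over 1.5 times, for cholesterol synthesis 0.36 without wild type replicate 1; immediate early genes 0.54 without wild type replicate 2; smooth muscle -0.77 without LAO1 replicate 1; B cells -0.85 without LAO1 replicate 2; smooth muscle -0.81 without IL4i1 replicate 1; B cells -0.8 and cholesterol synthesis 0.32 without IL4i1 replicate 2; absorptive colonocytes -1.11 and bile acid metabolism -1.23 without IL4i1 replicate 3; proliferation 0.56 without double replicate 1; inflammatory genes 0.79 without double replicate 2; fibroblasts 0.87 without double replicate 3. Ccl8 and Iigp1 failed with the trend and robust options, H2-Aa with quantile normalization, B cells and fibroblasts with that and over bright probes, and inflammatory genes over the latter.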

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

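The splits of the arrays into other groups were planned, while the interferon, Sh3d19 and clock tests were chosen after those results were seen.

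The effect of losing LAO1 differed between mice with and without IL4i1 for 51 probes, by the interaction term of the limma fit, and for 16 gene lists by camera. Of these lists 2, the interferon and enteroendocrine ones, passed with an estimated correlation and 3 with fry. The genes above the sum of the single losses were Mcpt1 (log2 13.12, of uncertain size), Iigp1 (9.22), Tgtp2 (8.8), Gm4841 (8.6), Mcpt2 (7.2, likewise uncertain), Irgm2 (7.2), Igtp (6.24), Gm12250 (6.13), Gbp2 (5.79), Tap1 (5.62), Ccl8 (4.67), Gbp7 (4.62), Cpa3 (4.57, likewise), Gbp3 (4.08), H2-Aa (3.82), Oasl2 (3.81), H2-Ab1 (3.64) and H2-Eb1 (3.47). Below it lay Sh3d19 (-3.43), Sult1c2 (-2.69), Nr1d1 (-2.6), Hao2 (-2.44) and Fam161a (-1.54). List means above the sum were 2.68 for the interferon response, 2.06 for MHC class II, 1.95 for mast cells, 0.9 for immediate early and heat shock genes, 0.89 for proliferation, 0.88 for macrophages, 0.67 for ATF4 targets, 0.56 for cholesterol synthesis, 0.51 for inflammatory genes, 0.47 for fibroblasts and 0.39 for T and innate lymphoid cells. Those below it were -0.84 for enteroendocrine genes, -0.74 for bile acid metabolism, -0.67 for absorptive colonocytes, -0.5 for B cells and -0.48 for smooth muscle. Without 1 array the B cell, fibroblast, inflammatory, smooth muscle, bile acid and absorptive colonocyte calls ended.

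Of 100 splits of the 12 arrays for the interaction, 1 gave as many genes, the real one with 51, and the next 3. They mix all genotypes, so they test for any group difference, not the interaction alone. For lists 8 gave at least the real 16, with 3 to 20 in the others, so chance was not excluded. The 10 splits of 6 arrays are too few for a share under 0.05 in the other comparisons. Against wild type their real and highest other gene counts were 5 and 0 (double), 1 and 0 (LAO1) and 3 and 3 (IL4i1). For the double they were 31 and 0 against the LAO1 and 106 and 3 against the IL4i1 knockout. In these, 1, 1, 2, 1 and 1 splits gave as many genes. For lists the real and highest other counts were 16 and 14, 9 and 13, 14 and 11, 14 and 19, and 19 and 17. The real count was reached in 1, 4, 1, 4 and 1 splits, and the lowest others were 8, 0, 4, 8 and 8. Preset camera thus passed lists in mixed groups too, and its p-values may be too small.

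The interferon response list was 1.9 higher (SE 0.2) in the double knockout than in the mean of the single knockouts. Pancreatic tissue in double knockout replicate 2 was argued against, since the difference without that array was 2.09 (SE 0.2). An equal rise of macrophages, monocytes and dendritic cells as the whole cause was argued against too. Their 18 bright markers were 0.54 higher (SE 0.22), 1.35 less than the interferon list (SE 0.37). A rise of only 1 of these cell types stayed open, as the mean pools them. A larger share of T and innate lymphoid cells stayed open, because only 9 of their markers were bright enough, fewer than the 10 set for the test; they were 0.45 higher (SE 0.16), 1.45 less (SE 0.25). The genotype, and an infection or different microbes in the cages of 1 genotype, may also lie behind the pattern and were not tested.

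Sh3d19 lay at 11.79 to 12.11 in wild type and 14.67 to 15.55 in the 9 knockout arrays, and was the 1 probe past the threshold between all knockouts and wild type (log2 3.06, SE 0.16, adjusted p = 7.97e-07). Additive effects of the 2 deletions were argued against by the interaction of -3.43 (SE 0.27). A chromosome segment of another mouse strain around Sh3d19 may change its probe's signal, and of the 20 nearest measured genes 0 differed in limma's test, with 1, Trim2 (log2 -0.74), at an unadjusted p under 0.05. That leaves the explanation open, since a segment need not change its other genes. A response to either deletion was not tested.

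Clock genes differed on average between wild type and the knockouts, with some overlap between their arrays. The mean of 4 activator genes differed by -1 (SE 0.25) and that of 11 output genes by 0.62 (SE 0.22). Between all knockouts and wild type 0 of them passed limma's test, and against wild type the clock list passed camera in the IL4i1 knockout alone (adjusted p = 0.643 with an estimated correlation). In the double knockout the output genes Nr1d1 (-1.08) and Hlf (-0.09) went the other way, Nr1d1 at 9.06 against 10.15 in wild type and 10.95 and 10.86 in the single knockouts. Output less activator was -3.46 to -2.09 in wild type and -2.15 to 0.01 in the knockouts; the difference of 1.62 had an exact two-sided permutation p of 0.00909 over 220 splits, which describes the pattern but does not test it, as the arms were set after the genes were seen. Tissue taken at another time of day is a candidate explanation that cannot be told apart from the genotype, because the collection time is not given in the sources used here.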

How the results depend on the processing

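Fits without the arrays that stood apart, in comparisons that do not use them, were chosen after seeing the data.

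Probes near the bottom of the range, such as Lao1, show no fall. Across settings that kept all arrays, values of named genes other than Lao1 held their direction and side of the threshold 1670 times, moved past it 22 times, lost it 10 times and reversed 2 times. List values did so 334 times and lost the threshold 194 times. Without 1 array, the values of these genes held 3235 times, moved past the threshold 43 times, lost it 125 times and reversed 16 times, and list values held 593 times, lost it 111 times and turned in camera's direction 5 times, the B cell mean of -0.01 not among them. The fit to the compared arrays only was not possible for the interaction.

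Trend and robust options gave 11 genes for the double knockout against wild type and 8 for the IL4i1 knockout, and ended the calls of Iigp1, Tgtp2, Upp1 and Ccl8 given with their comparisons. Array weights gave 18 and 11, and 60 for the double against the LAO1 knockout. An unadjusted p under 0.05 with at least 2-fold gave 264, 82 and 327 genes for the double, LAO1 and IL4i1 knockouts against wild type, 280 and 549 for the double against the LAO1 and IL4i1 knockouts, and 802 for the interaction. An adjusted p under 0.1 gave 13 and 9 for the double and IL4i1 knockouts against wild type and 57 and 169 for the double against the LAO1 and IL4i1 knockouts. Only the arrays compared gave 2 and 33 for the double against wild type and the IL4i1 knockout. More genes pass the looser thresholds by construction; for the other settings the cause was not tested. Without IL4i1 knockout replicate 2 the double knockout against wild type had 8 genes.

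With an estimated correlation camera passed 0, 0, 0, 1, 2 and 2 lists in the 6 comparisons in the order of the report, and fry passed 1, 0, 0, 1, 3 and 3. The estimated correlation widens camera's error by construction, and for fry the cause was not tested. The similarity of the single knockouts was 0.528 over probes above the 40th percentile.

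The replicate block gave 6, 1, 3, 43, 166 and 60 genes. Sulf2, Mcpt2, Mthfd2, Ccl8 and the immediate early list each did not pass with it in 1 comparison where they otherwise did. Of 18 pairs of arrays with the same number, 7 correlated above 0.1 (-0.142 to 0.218, median 0.0605, against -0.035 for other numbers). Of 12 arrays 5 correlated best with their own number, which leaves weak pairing open.

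Leaving out 1 array at a time gave 1 to 38, 1 to 4, 2 to 6, 11 to 68, 46 to 174 and 37 to 74 genes in the 6 comparisons, and 13 to 18, 7 to 10, 9 to 14, 12 to 16, 15 to 22 and 13 to 20 lists. The similarity ran from 0.523 to 0.685, against 0.6 to 0.602 simulated with 2 shared wild type arrays. Lao1 ran from 0.22 to 0.52, -0.17 to 0.17, -0.02 to 0.28, 0.23 to 0.51, 0.16 to 0.33 and 0.07 to 0.42. In the double knockout against wild type, ranges that crossed 0 were Ahrr (-0.08 to 0.27), Cela3b (-0.01 to 4.47), Cyp1a1 (-0.27 to 0.07), Kynu (-0.1 to 0.15), Lcn2 (-0.16 to 3.08), Reg3g (-1.02 to 5.61) and the acinar list (-0.38 to 4.21). Against the LAO1 knockout they were Cela2a (-0.08 to 5.23), Cpa1 (-0.09 to 6.53), S100a8 (-0.06 to 1.28) and the acinar list (-0.62 to 3.97). Against the IL4i1 knockout they were Cela2a (-0.04 to 5.28), Reg1 (-0.03 to 5.16), Jchain (-0.13 to 2.71) and the acinar list (-0.42 to 4.16). In the single knockouts they were smooth muscle (-0.46 to 0.03) and B cells (-0.01 to 0.7) for LAO1, and B cells for IL4i1 (-0.09 to 0.61). Kynu was also -0.03 with quantile normalization and -0.01 with each array centred on its median, and Lao1 in the LAO1 knockout -0.02 with quantile normalization. For the reversed values and changed counts without 1 array the cause was not tested.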

Other observations

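Amino acid transporters did not pass camera in the double knockout against the IL4i1 knockout (adjusted p = 0.671), and 0 members passed over all genes in limma's test, against 4 higher and 2 lower at an unadjusted p under 0.05. Its median was -0.01 and its mean 0.25. Adjusted over the list alone Slc7a5 (log2 2.59) and Slc3a2 (1.42), which together form a carrier of large neutral amino acids, and the cystine carrier Slc7a11 (2.1) were higher. Slc6a14 (-1.47) and Slc1a5 (-0.8) were lower. These genes were chosen after their values were seen.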
